A study of Musca domestica with 28 samples.

How the data were processed

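Gene expression was measured by sequencing of poly(A) RNA from adult female house flies (Musca domestica), per the labels' protocols. Each fly was fed a droplet of 2 µL that held 460000 CFU of a Pseudomonas aeruginosa strain, 380000 CFU of an Escherichia coli strain, or the corresponding broth medium, and was dissected 4 h later into the gut (the alimentary canal) and the body (the rest of the carcass). Each library came from a pool of 3 flies. In the E. coli experiment tissues were pooled before RNA extraction, and in the P. aeruginosa experiment RNA of single flies was pooled after extraction, so the bacterium, its broth and the pooling step cannot be separated between the experiments. The labels gave 28 libraries in 8 groups, with 4 libraries per group in the P. aeruginosa experiment and 3 in the E. coli experiment.

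The deposited count tables hold estimated counts, 1 value per gene and library, which the authors made with kallisto 0.44.0 per the submitters' processing notes and which are whole numbers. A second deposited table per experiment holds TPM, a length-scaled score that the authors rounded to whole numbers in nearly all gene rows. The transcript reference and the step from transcripts to genes are not given in the sources used here. An estimated count divides reads that fit several similar transcripts among them, so values of close paralogs are not independent of each other. Each table has 14888 rows, of which 5 name no gene and were left out, leaving 14883 genes. The row LOCNULL, which names no gene, held between 1.28% and 2.28% of the counts of a library, and between 2.63% and 23.6% of its TPM.

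Columns were assigned to groups by their header names and by agreement of the count and TPM columns. Among the E. coli counts, 2 body columns shared a header name, so both were assigned to the infected body group without a replicate letter. Compared with the TPM columns, 1 matched replicate A best (r = 0.987, next 0.970) and the other replicate B (r = 0.986, next 0.965), and these letters were used in added alternatives only. Replicate numbers in the headers were read as the letters of the labels. Libraries that carried the same letter did not consistently resemble each other most, and the letters were not used as pairs except as an alternative. Of the 14883 identifiers 12948 were found in the gene table at hand, and 57 had a symbol other than a LOC number. The 32 gene lists that were fixed before the data were examined relied on product names, which that table does not hold, so they could not be built. In their place 37 genes with a symbol were put into 8 lists after the values had been opened, namely antimicrobial effectors, serpins, the cytochrome P450 system, glutathione S-transferases, superoxide dismutases, chaperones, neuronal and sensory genes, and female germline and yolk. Tests on these lists are therefore not tests of lists fixed in advance. No genome came with the data and no coordinates are given.

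Estimated counts were analysed with edgeR 4.0.16 (TMM scaling, filterByExpr by group, robust quasi-likelihood F tests) and limma 3.58.1 in R 4.3.3. Each experiment was fitted with 1 mean per group, and comparisons between the experiments used a joint fit of all 8 groups. P values were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison, and an adjusted p under 0.05 counted as a call. Errors of log2 fold changes are standard errors of that fit, and intervals are at the 95% level. Levels are CPM, counts scaled by library size after TMM scaling, given as mean ± SD over libraries. For diptericin, and for lysozyme in the P. aeruginosa experiment, whose counts were few in at least 1 tissue, the ratio of summed scaled counts is given with its exact counting interval, which covers counting error only. Lists of at least 3 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Differences across genes between the experiments, and the classes of genes described in the closing section, were tested by relabelling the libraries.

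Alternatives were RLE scaling, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0 (Wald test), limma-trend on log2 of TPM with a pseudocount of 1, fits of the compared groups only, the joint fit, a block for the replicate letter, a threshold of 2-fold, and leaving out each library in turn. Alternatives added after the data had been seen were a covariate for bcd RNA, removal of libraries with or without bcd RNA, 2 residual components as covariates, blocks within parts of the E. coli experiment, and blocks over that whole experiment with the letters of the TPM match. Besides the 10 comparisons planned before the data were examined, 3 were added afterwards, and these are described in the closing section only. Genes without a product name were named by a rule fixed in advance, at most 2 identifiers per direction: those with the largest change among called genes, or, for interactions and differences between bacteria, those with the smallest p. The main edgeR fit called no gene in an infection comparison, so the identifiers named there are those with its smallest p. They were chosen after their values had been seen.

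The edgeR step was tested on simulated counts with known changes. They were drawn from a single mean per gene over all libraries and from the dispersions and library sizes of the real data. Libraries were drawn independently, without the differences that many genes share between real libraries. Recovery and false calls in the real data may therefore differ from those given here. For P. aeruginosa guts it recovered 20.9% of genes changed 2-fold and 81.2% of genes changed 4-fold among 11535 genes, with 2 false calls. For E. coli guts it recovered 53.0% and 80.0% among 11217 genes, with 3 false calls. For the difference of the P. aeruginosa response between tissues it recovered 1.56% and 39.4% among 11512 genes, and for the difference of the gut response between bacteria 7.46% and 42.4% among 11752 genes. The columns hold 14598223 to 21023861 counts per library.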

Results

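The data are estimated counts per gene in 28 libraries of house fly gut or body, 16 from an experiment with P. aeruginosa and 12 from an experiment with E. coli. Each experiment had flies fed bacteria and flies fed broth medium, with 4 libraries per group in the P. aeruginosa experiment and 3 in the E. coli experiment. Total counts ran from 15064057 to 21023861 in the P. aeruginosa experiment and from 14598223 to 17966462 in the E. coli experiment. Between 11325 and 12860 genes had counts in a library. Most genes carry an identifier only, so the description rests on 37 genes with a symbol. The title of the series asks which immune effectors house flies express constitutively, that is, without infection. The transcription factors that the title also names were not analysed here.

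In control flies of both experiments, the antimicrobial effectors defensin-1 and lysozyme were higher in the gut, and 3 receptor and channel genes (nAChRbeta3, IR25a and para-like), 3 serpins and the yolk protein yp3 were higher in the body. Defensin-1, a secreted antibacterial peptide, stood at 6.61 ± 7.83 CPM in the gut and 0.506 ± 0.270 CPM in the body of P. aeruginosa controls (n = 4 each, log2 fold change 3.70 ± 1.05, edgeR adjusted p = 0.00961). In the E. coli controls it stood at 10.6 ± 2.89 and 0.788 ± 0.584 CPM (n = 3 each, log2 fold change 3.74 ± 0.48, adjusted p = 3.8e-05). Lysozyme, an enzyme that cleaves bacterial cell walls, stood at 24.0 ± 21.3 CPM in P. aeruginosa control guts, whose bodies held 1 count in total, a ratio of 1458 with a counting interval of 261 to 57606. In the E. coli controls it stood at 44.3 ± 14.7 CPM in the gut and 0.228 ± 0.395 CPM in the body (log2 fold change 7.54 ± 1.00, adjusted p = 8.6e-05). Diptericin, another antibacterial peptide, had too few counts for the test. Its 20 counts in P. aeruginosa control guts against 3 in the bodies gave a ratio of 6.26 (interval 1.86 to 32.9), and its 26 against 4 counts in the E. coli controls gave 7.42 (2.58 to 29.3). Without gut control A and body control A, the call for defensin-1 in the P. aeruginosa controls ended at log2 2.60 and adjusted p = 0.060, and over its 18 alternatives the adjusted p ran from 0.00027 to 0.060.

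Enzymes that act on foreign compounds went both ways between the tissues. Of the 10 genes of the cytochrome P450 system, 4 were higher in the gut and 3 in the body of P. aeruginosa controls, and 7 and 1 in the E. coli controls, where 1 of the 7, CPR, changed sign on TPM. CYP6A24 reached 4223 ± 1666 CPM in the gut and 410 ± 203 CPM in the body of P. aeruginosa controls (log2 fold change 3.36 ± 0.40), and CYP12A1, CYP6A40 and CYP6A1 were higher in the gut of both experiments too. CYP6D8 was higher in the body of both, with log2 fold changes of -2.36 ± 0.54 and -2.59 ± 0.44. Among glutathione S-transferases, which conjugate foreign compounds, Gst-2 was higher in the gut (log2 3.77 ± 0.35 and 4.09 ± 0.36) and GST higher in the body (log2 -3.89 ± 0.48 and -4.75 ± 0.22). Of 3 superoxide dismutases, SOD2 was higher in the body in both experiments (log2 -1.77 ± 0.17 and -1.62 ± 0.11). The chaperone HSP70 was higher in the gut, with log2 fold changes of 0.72 ± 0.18 and 1.48 ± 0.12. All differences named so far in this paragraph had an adjusted p under the threshold with edgeR, with n = 4 per group in the P. aeruginosa experiment and n = 3 in the E. coli experiment. On TPM, the E. coli values of CYP12A2, CYP6G4, CPR, SOD, CCT-eta, CCT-zeta and pdf, and the P. aeruginosa values of SOD and SOD1, changed sign. Not all of these had passed with edgeR: SOD and SOD1 had not in the P. aeruginosa controls, nor had CYP12A2, CYP6G4 and pdf in the E. coli controls. Of the 5 chaperones, 2 had not passed in the E. coli controls either.

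Most nervous system genes lay on the body side. All 5 that could be tested were higher in the body of P. aeruginosa controls, and 4 of 5 in the E. coli controls. There pdf, a circadian neuropeptide, did not pass the test (log2 0.61, adjusted p = 0.351) and changed sign on TPM, again without passing (-0.19, adjusted p = 0.437). The nicotinic acetylcholine receptor subunit nAChRbeta3 stood at 55.1 ± 7.99 CPM in the body and 4.15 ± 1.70 CPM in the gut of P. aeruginosa controls (log2 fold change gut against body -3.73 ± 0.31), and at -4.16 ± 0.28 in the E. coli controls. The sodium channel para-like had log2 fold changes of -2.65 ± 0.54 and -5.21 ± 0.23, and acetylcholinesterase (ace) of -4.09 ± 0.53 and -3.59 ± 0.37. With camera at the preset correlation the list lay lower in the gut (adjusted p = 0.00327 and 0.0227), and with an estimated correlation the adjusted p was 0.152 and 0.422. No other list passed camera in these comparisons. Fry asks whether the members of a list shift in a common direction, not whether they shift more than other genes. With it the neuronal genes (adjusted p = 3.6e-07 and 9.8e-06) and serpins (7.1e-05 and 2.0e-05) passed toward the body in both experiments. Chaperones (0.00925 and 3.8e-04) and the P450 system (0.0189 and 2.5e-05) passed toward the gut in both. The median P450 gene nevertheless lay at log2 -0.31, on the body side, in the P. aeruginosa controls, so no direction common to its members was shown there. Superoxide dismutases passed toward the body in the P. aeruginosa controls alone (fry adjusted p = 0.00119). In its form for changes in either direction, fry passed every tested list in the E. coli controls (largest adjusted p = 0.00831). In the P. aeruginosa controls that form passed all lists but the chaperones (adjusted p = 0.116). Serpins, inhibitors of serine proteases, were higher in the body for 3 of 4 members in the P. aeruginosa controls and for 4 of 4 in the E. coli controls, with SPN13 at log2 -4.42 ± 0.71 and -8.26 ± 0.73. The yolk protein yp3 stood at 1213 ± 637 CPM in the body and 129 ± 73.0 CPM in the gut of P. aeruginosa controls, and at 839 ± 41.8 and 31.8 ± 38.0 CPM in the E. coli controls. The oocyte transcript bcd was higher in the body of the E. coli controls (log2 -4.09 ± 0.85), but gave 1.94 ± 1.92 in the P. aeruginosa controls, where it did not pass the test and its level ranged from 0 to 32.2 CPM among control guts.

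**Figure D1:**
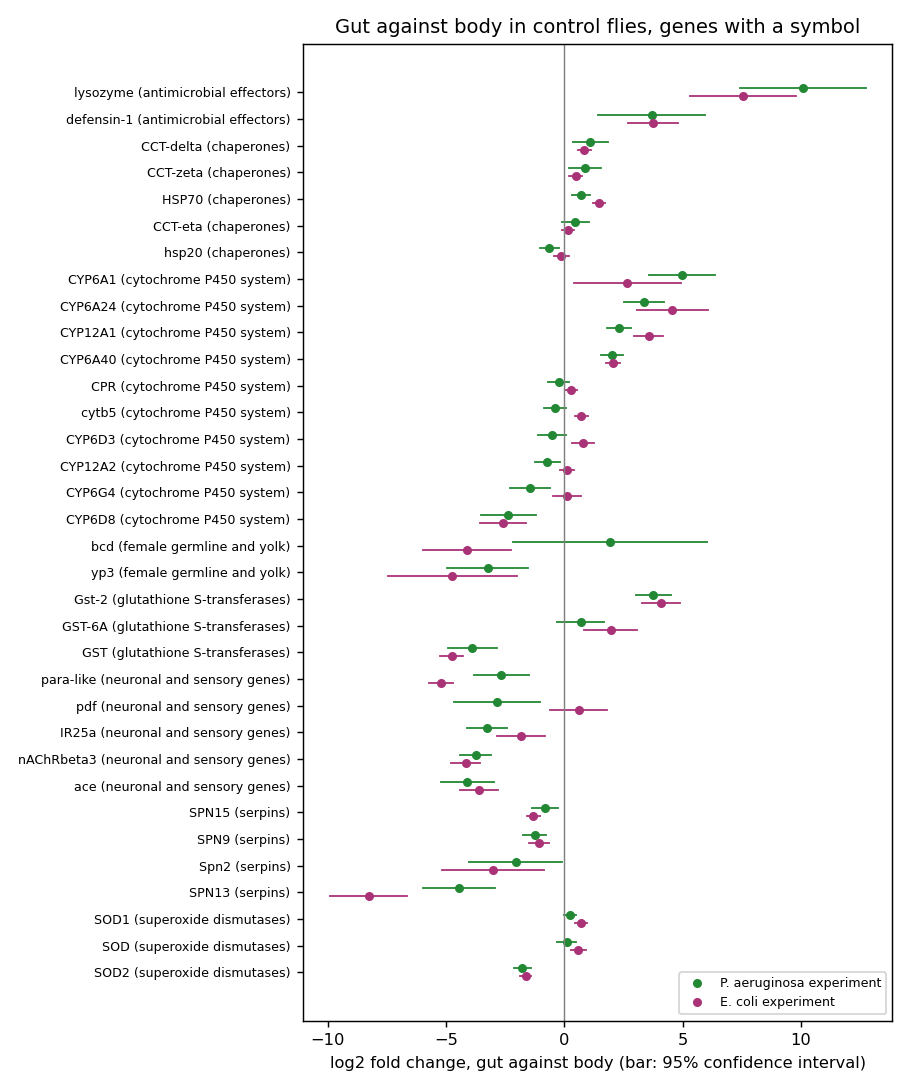
Log2 fold change of control gut against control body for each tested gene with a symbol, by list. Points are edgeR estimates and bars 95% confidence intervals, for the P. aeruginosa experiment (n = 4 per group) and the E. coli experiment (n = 3 per group). Defensin-1 lies at 3.70 and 3.74, and nAChRbeta3 at -3.73 and -4.16.

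Over all genes, edgeR called 2199 higher in the gut and 3299 higher in the body of the P. aeruginosa controls, of 11719 tested. In the E. coli controls it called 3411 and 3911, of 11476 tested. Of the 11346 genes tested in both experiments, 1982 were called gut-higher and 2616 body-higher in both, where independent calls would give 652 and 1074, and 15 were called in opposite directions. The experiments were not alike for genes that follow the oocyte transcript bcd. The 200 closest to it over the P. aeruginosa guts had a median log2 fold change of 1.62 in the P. aeruginosa controls, with 1 called gut-higher and 1 body-higher. In the E. coli controls it was -3.18, with 173 of 194 called body-higher. The largest gut-side changes among called genes with a mean TPM of at least 100 belonged to LOC101900762 and LOC101894187 in the P. aeruginosa experiment and to LOC101895551 and LOC101890748 in the E. coli experiment. LOC101887335 was among the 2 largest on the body side in both. On TPM, where the median of all genes moved by -0.26 in the P. aeruginosa and -0.46 in the E. coli comparison on the log2 scale, the gut-higher share of the calls was 25.7% in place of 40.0%, and 21.6% in place of 46.6%.

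The constitutive level of the 3 effectors was highest in the gut for lysozyme. By mean TPM, lysozyme stood above 92.9% of all genes in P. aeruginosa control guts and above 95.6% in E. coli control guts, defensin-1 above 79.9% and 89.0%, and diptericin above 34.4% and 48.7%. The median percentile of the 3 was 79.9 and 89.0 in the guts and 20.5 and 29.9 in the bodies. Random lists of 3 genes had a median as high in 11% of draws for the P. aeruginosa and 3.32% for the E. coli guts, and in 88.7% and 72.6% for the bodies. TPM gives short transcripts more weight than CPM: on CPM the gut medians were 47.8 and 61.2.

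**Figure D2:**
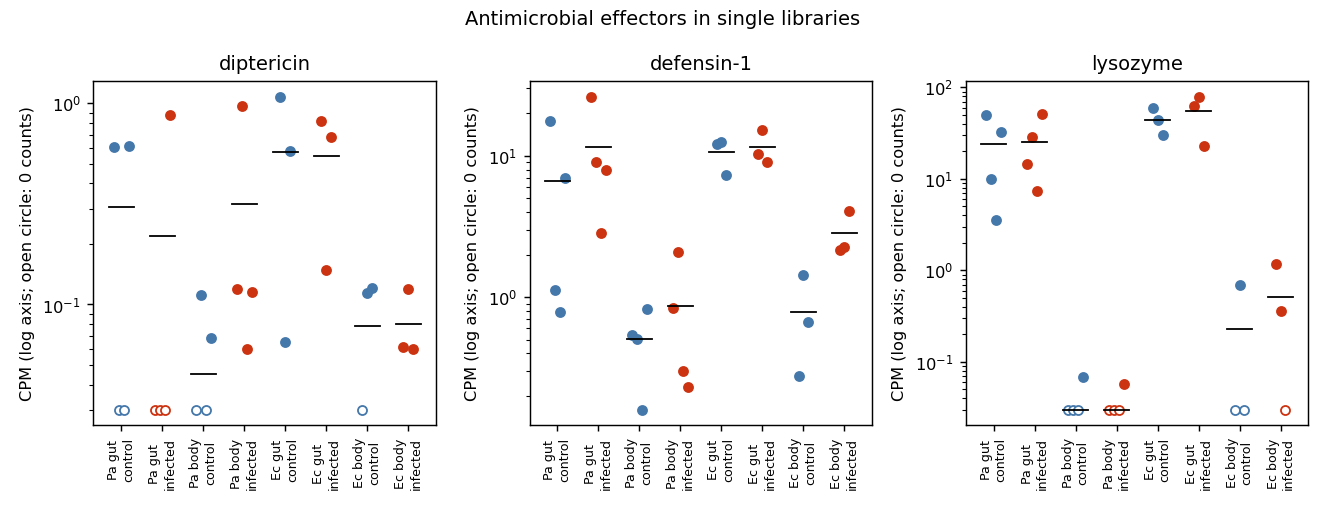
CPM of diptericin, defensin-1 and lysozyme in each of the 28 libraries, on log axes, with bars at the group means. Pa marks the P. aeruginosa and Ec the E. coli experiment, and open circles mark libraries with 0 counts. Lysozyme was at least 3.55 CPM in P. aeruginosa control guts and stayed at or under 0.0682 CPM in the bodies of that experiment.

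Feeding P. aeruginosa was compared with broth medium to ask which genes respond within 4 h. In the gut, the effectors did not differ beyond the spread between libraries: defensin-1 stood at 11.5 ± 10.2 CPM in infected and 6.61 ± 7.83 CPM in control guts, and lysozyme at 25.5 ± 19.4 and 24.0 ± 21.3 CPM (n = 4 each). Diptericin had 15 counts in infected and 20 in control guts. The yolk protein yp3 stood at 18.9 ± 13.4 CPM in infected and 129 ± 73.0 CPM in control guts (log2 fold change -2.77 ± 0.79, edgeR adjusted p = 0.760, and 0.0759 adjusted over the genes with a symbol alone). The sodium channel para-like, at 46.0 ± 18.2 and 156 ± 139 CPM, gave log2 -1.76 ± 0.52 with the same adjusted values. Both genes are body-higher, and the 741 genes at least 8-fold higher in E. coli control body than gut had a median log2 difference of -0.63 in these guts. No member of any list passed the test, and no list passed camera, where the smallest adjusted p was 0.301.

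Over all genes, edgeR called 0 of 11719 in P. aeruginosa guts, with 596 at an unadjusted p under 0.05 where chance alone gives about 586. DESeq2 called 23 (4 higher, 19 lower) and limma-trend on TPM called 0. The smallest p values among higher genes belonged to LOC101895457 (log2 1.31 ± 0.26) and LOC101898316 (2.91 ± 0.62), and among lower genes to LOC101890898 (-2.53 ± 0.40) and LOC101890151 (-1.79 ± 0.35). LOC101898316 and both lower genes were also far higher in the body than in the gut: LOC101890898 stood at 157 ± 30.6 CPM in control body and 4.87 ± 1.83 CPM in control gut. LOC101898316 had only 6 counts in all control and 51 in all infected guts. Infected and control libraries did not overlap for 1.34% of genes, where chance gives 2.86%. In simulated libraries, which lacked the shared structure of the real ones, changes of 2-fold were recovered for 20.9% of genes. How many real changes of that size were missed is not known.

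In the body of flies fed P. aeruginosa, neither defensin-1 nor lysozyme stood apart from the controls. Defensin-1 stood at 0.864 ± 0.861 CPM in infected and 0.506 ± 0.270 CPM in control bodies (n = 4 each), and lysozyme had 1 count in each group. Diptericin had 18 counts in infected and 3 in control bodies, too few for the test in the fit of this experiment. Among genes with a symbol, the smallest edgeR p was that of CYP6A24, at 244 ± 70.1 CPM in infected and 410 ± 203 CPM in control bodies (log2 -0.75 ± 0.37, adjusted p = 1). EdgeR called 0 of 11719 genes, with 270 at an unadjusted p under 0.05, fewer than the about 586 that chance alone gives. DESeq2 called 1 and limma-trend on TPM called 1. No list passed camera, where the smallest adjusted p was 0.129. LOC105262415 (log2 6.82 ± 1.62) and LOC101896542 (2.44 ± 0.62) had the smallest p among higher genes, and LOC101894344 (-1.29 ± 0.28) and LOC101893779 (-0.81 ± 0.23) among lower genes. The mean of LOC105262415 in infected bodies rested on replicate B, at 42.3 CPM. LOC101896542 stood at 0.74 ± 0.47 CPM in infected and 0.13 ± 0.08 CPM in control bodies, but at 54.4 ± 24.5 CPM in control guts.

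Feeding E. coli asked the same question for the other bacterium. In the gut, defensin-1 stood at 11.5 ± 3.26 CPM in infected and 10.6 ± 2.89 CPM in control libraries, lysozyme at 55.0 ± 29.1 and 44.3 ± 14.7 CPM, and diptericin had 25 and 26 counts (n = 3 each). The yolk protein yp3 stood at 0.350 ± 0.240 CPM in infected and 31.8 ± 38.0 CPM in control guts (log2 -6.44 ± 1.52, edgeR adjusted p = 0.314), and its control libraries ran from 0.128 to 73.9 CPM. The receptor subunit nAChRbeta3 stood at 0.900 ± 0.385 and 2.19 ± 0.763 CPM (log2 -1.29 ± 0.34, adjusted p = 0.336). Both had an adjusted p of 0.0487 over the 34 tested genes with a symbol. These genes are body-higher, and the 506 genes at least 8-fold higher in P. aeruginosa control body than gut had a median log2 difference of -0.47 in these guts.

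Over all genes, edgeR called 0 of 11476 in E. coli guts, with 1119 at an unadjusted p under 0.05 where chance gives about 574, and a smallest adjusted p of 0.0875. DESeq2 called 115 (19 higher, 96 lower) and limma-trend on TPM called 25 (5 higher, 20 lower). Of the 96 lower DESeq2 calls, 70 were called body-higher in the P. aeruginosa controls, which are other libraries. LOC101891119 stood at 44.0 ± 3.23 CPM in infected and 11.2 ± 2.14 CPM in control guts and had 0 counts in the bodies (log2 1.98 ± 0.18), and LOC101899302 stood at 562 ± 190 CPM in infected and 192 ± 27.7 CPM in control guts (1.55 ± 0.23). LOC101896532 (-1.19 ± 0.17) and LOC101887234 (-3.80 ± 0.61) had the smallest p among lower genes. Leaving out control gut C, the library with 0.128 CPM of yp3, gave 54 calls (5 higher, 49 lower), and leaving out infected gut A gave 8. Infected and control libraries did not overlap for 12.7% of genes, where chance gives 10%. No list passed camera, where the smallest adjusted p was 0.0864 for both the P450 system and the neuronal genes, and it was 0.546 with an estimated correlation.

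In the body of flies fed E. coli, defensin-1 had the smallest p among genes with a symbol. It stood at 2.83 ± 1.09 CPM in infected and 0.788 ± 0.584 CPM in control bodies, 2.14 to 4.09 against 0.277 to 1.42 CPM without overlap (log2 1.84 ± 0.49, n = 3 each, edgeR adjusted p = 1 over all genes and 0.112 over the genes with a symbol). Over 15 alternatives its log2 fold change ran from 1.43 to 2.59 and its adjusted p from 0.130 to 1. Lysozyme had 25 counts in infected and 12 in control bodies, and diptericin 4 in each. EdgeR called 0 of 11476 genes, with 409 at an unadjusted p under 0.05, fewer than the about 574 that chance alone gives. DESeq2 called 7 and limma-trend on TPM called 20. In infected body C the row LOCNULL, which names no gene, held 23.6% of the TPM, against 7.41% to 10.4% in the other E. coli bodies. Whether this bears on the TPM calls was not tested. LOC101899490 (log2 3.00 ± 0.52) and LOC101898980 (2.02 ± 0.40) had the smallest p among higher genes, and their levels in control guts were 223 ± 32.9 and 315 ± 53.2 CPM. The smallest p among lower genes belonged to LOC101901386 (-1.33 ± 0.25) and LOC101887296 (-2.66 ± 0.47). In control guts the first stood at 3072 ± 289 CPM and the second had 0 counts. No list passed camera, where the smallest adjusted p was 0.492. Without overlap were 10.5% of genes, where chance gives 10%.

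The response was then compared between tissues. For yp3 the gut response lay below the body response by log2 -3.20 ± 1.07 with P. aeruginosa and -6.46 ± 1.84 with E. coli, and for defensin-1 in the E. coli experiment by -1.73 ± 0.63, none of them past the threshold (edgeR adjusted p = 0.973, 0.859 and 0.859). EdgeR called 0 genes whose P. aeruginosa response differed between tissues, with 341 at an unadjusted p under 0.05, where chance gives about 586. DESeq2 called 3 and limma-trend on TPM called 0. For E. coli edgeR called 0, with 626 at an unadjusted p under 0.05, where chance gives about 574. DESeq2 called 23 and limma-trend on TPM called 0. The cytochrome P450 list passed camera for P. aeruginosa, higher in the gut response than in the body response (adjusted p = 0.0415, adjusted p = 0.866 with an estimated correlation, and no list passed fry, smallest adjusted p = 0.945), with a median difference of 0.29 over its 10 members. The smallest p values belonged to LOC101887335 and LOC101898316 (higher in gut response) and LOC101890898 and LOC101890610 (lower) for P. aeruginosa. The 2 higher ones were near the floor in the gut. LOC101887335 had 1 count in all control and 12 in all infected guts, and LOC101898316 had 6 and 51. Control bodies held 588 ± 166 and 4687 ± 1466 CPM of them. For E. coli they belonged to LOC101901386 and LOC101898189 (higher) and LOC101898487 and LOC101888673 (lower).

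The response was also compared between the bacteria, a contrast of responses because each bacterium had its own controls. For yp3 the gut response to P. aeruginosa lay above that to E. coli by log2 3.69 ± 1.55, and for para-like below it by -1.40 ± 0.65, neither past the threshold (edgeR adjusted p = 1 for both). In the gut edgeR called 0 of 12005 genes, with 367 at an unadjusted p under 0.05, where chance gives about 600. DESeq2 called 20 and limma-trend on TPM called 0. In the body edgeR called 0, with 206 at an unadjusted p under 0.05, where chance gives about 600. DESeq2 called 4 and limma-trend on TPM called 2. No list passed camera in either tissue, where the smallest adjusted p was 0.718 in the gut and 0.127 in the body. In the gut the smallest p values belonged to LOC101887234 and LOC101887671 (higher with P. aeruginosa) and LOC101889291 and LOC101896244 (lower), and in the body to LOC101897775 and LOC101896409 (higher) and LOC101887541 and LOC101894344 (lower). Broth and pooling also differed between the experiments.

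**Figure D3:**
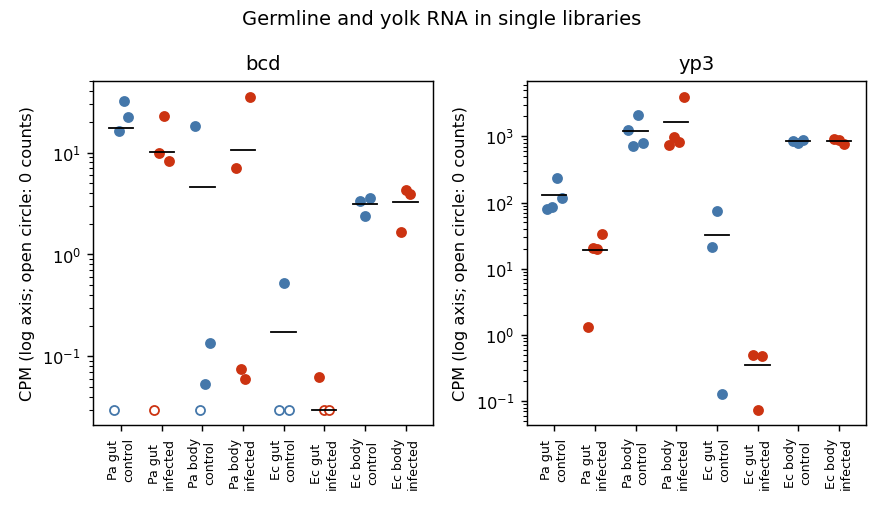
CPM of bcd, a transcript of the oocyte, and yp3, a yolk protein, in each of the 28 libraries, on log axes, with bars at the group means. Pa marks the P. aeruginosa and Ec the E. coli experiment, and open circles mark libraries with 0 counts. A bar level with the open circles stands for a mean at or under that level. In P. aeruginosa guts bcd had 0 counts in 2 libraries and from 8.35 to 32.2 CPM in the other 6, and yp3 in E. coli infected guts stayed at or under 0.501 CPM.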

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

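All tests of the bcd pattern and both redrawings of the experiments' tissue difference were chosen or settled only after the result, or a principal component analysis that showed it, had been seen.

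Among 164 sets of 4 libraries in the P. aeruginosa experiment, 12 had a library whose gap to the nearest other exceeded 0.829 of the range of the set. Chance gives about 1 in 20, here 8.2. Gut control A stood apart for CYP6G4 (934 CPM), CCT-eta (156 CPM) and CCT-zeta (160 CPM), and body control A for CCT-zeta (190 CPM) and bcd (18.3 CPM). Infected gut C was lowest for CYP12A1 (10.6 CPM) and CYP6A40 (45.0 CPM), infected gut D for SOD1 (14.1 CPM), and infected body A for Gst-2 (10.99 CPM). Infected body D was highest for yp3 (3979 CPM), infected body B for LOC105262415 (42.3 CPM), and infected gut A for LOC101896542 (133 CPM).

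The oocyte transcript bcd divided P. aeruginosa libraries of 1 group: it had 0 counts in 2 guts and 8.35 to 32.2 CPM in the other 6, and it exceeded 1 CPM in 3 of the 8 bodies. Too few counts are excluded, since 3 counts allow at most 0.0295 of the lowest level in the other guts. An exchange of gut and body libraries is argued against by lysozyme, whose lowest gut lay 52.1 times above the highest body. For a response to P. aeruginosa, infected and control guts differed by 0.0797 of the range within the controls. Control gut A, without bcd, sets that range, so the ratio does not decide on a response. The 2 guts without bcd were control A and infected A. In the other guts log2 CPM ran from 4.03 to 5.01 in controls and from 3.08 to 4.51 in infected libraries. A candidate explanation is ovary tissue that went with the gut in some pools and with the carcass in others: the 200 genes closest to bcd over the guts had a median correlation of 0.973 with it over the bodies, where all genes had -0.02, and a median log2 fold change of -3.18 between gut and body in the E. coli controls. In the P. aeruginosa controls their median log2 fold change was 1.62. Over the 8 pools that share a treatment and a letter, bcd in gut and body gave Pearson r = -0.714 (exact p = 0.0530) and Spearman rho = -0.714 (exact p = 0.0576), r = -0.642 without the 2 farthest pools, with a pairing by letter that the data do not otherwise bear out, so this remains a hypothesis.

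The difference between gut and body in controls differed between the experiments for 6 genes in the joint edgeR fit (1 higher and 5 lower, with 3070 at an unadjusted p under 0.05), a comparison added afterwards. The higher gene was LOC101895268 (log2 3.25 ± 0.56), and LOC101896946 (-2.71 ± 0.36) and LOC101897010 (-1.36 ± 0.22) were among the lower ones. DESeq2 called 1056 and limma-trend on TPM 140, and leaving out P. aeruginosa gut control A gave 2537 and body control A 1371. Tissue labels were redrawn within each experiment first, and 6 of 50 splits gave as many genes, the highest of the others 6486. After that result was seen, experiment labels were redrawn within each tissue, and 2 of 50 splits gave as many, the highest of the others 1184. In all 5 of the other large splits of the first scheme the E. coli labels were all kept or all exchanged, with 50% or 75% of the P. aeruginosa labels kept, so the scheme itself turned the tissue difference into a difference between experiments and its share decides nothing. The second scheme redraws every difference between the experiments along with the one asked about, so its 4% is not taken to exclude chance, which stays open.

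The cytochrome P450 list passed camera for the difference of the P. aeruginosa response between tissues (adjusted p = 0.0415, 0.866 with an estimated correlation, not with fry) and for the difference between the experiments' control tissues (adjusted p = 0.0105, 0.567 with an estimated correlation, 0.0293 with fry). Superoxide dismutases passed fry alone for the latter (adjusted p = 0.0310).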

How the results depend on the processing

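Alternatives added after the data had been seen were the bcd covariate, the removal of libraries by bcd, the 2 residual components, the E. coli blocks, TPM rescaled without unnamed rows, and every alternative of the 3 added comparisons. The cause of a change was not tested except where stated.

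Calls between gut and body of controls ran from 4740 to 6636 in the P. aeruginosa and from 6802 to 7883 in the E. coli experiment, and with a 2-fold threshold they were 3966 and 4943, all within 1.5 times of 5498 and 7322. For the infection comparisons, in which edgeR called 0 genes, DESeq2 called 23 (P. aeruginosa gut), 1 (P. aeruginosa body), 115 (E. coli gut) and 7 (E. coli body), and 3, 23, 20 and 4 for the differences between tissues with P. aeruginosa and E. coli and between bacteria in gut and body. Limma-trend on TPM called 1 in P. aeruginosa body, 25 in E. coli gut, 20 in E. coli body and 2 between bacteria in the body. On TPM the median of all genes moved by -0.12 in P. aeruginosa gut, -0.15 in E. coli body and 0.10 for the difference between tissues with E. coli (log2), and of the 20 E. coli body calls 19 were lower. In E. coli guts 1 gene was called with no filter, 1 with the 2 compared groups alone, and 1 with a block in the gut libraries; 1 was called in P. aeruginosa guts without the libraries lacking bcd, and 2 in E. coli bodies with 2 residual components.

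With 2 residual components 375 genes were called in P. aeruginosa guts (327 higher, 48 lower). Of the 35 splits of the 8 guts, 16 gave as many with the same correction, the others had a median of 296.5 calls and a highest of 5053, so the corrected fit calls genes where no infection contrast exists and its count is not taken as a response.

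Leaving out each library in turn gave 0 to 2 calls in P. aeruginosa gut (2 without control C, 1 without infected D), 0 to 1 in P. aeruginosa body (1 without infected C), 0 to 54 in E. coli gut (54 without control C, 8 without infected A, 2 without infected C), 0 to 1 in E. coli body (1 without control C or infected 1b), 0 to 16 for the E. coli difference between tissues (16 without control gut C, 3 without infected gut A, 1 without infected body 1b), and 0 to 1 for the difference between bacteria in the body (1 without P. aeruginosa infected C). No list of the infection comparisons passed camera in the main analysis, and 0 passed fry. With camera 1 passed with no filter, 2 with the replicate block, and 0 to 2 with a library left out (2 without E. coli infected body 1b, control gut C or infected gut B, and 1 without P. aeruginosa control body C or infected gut D, or E. coli control body B, infected body C, control gut B, infected gut A or infected gut C).

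For the added comparisons, the 6 genes whose tissue difference differed between experiments became 3 with RLE, 1056 with DESeq2 and 140 with limma-trend on TPM, and 1 to 2537 with a library left out (2537 without P. aeruginosa gut control A, 1371 without body control A and 26 without gut control C). It was 1, 2 or 3 without P. aeruginosa body control B, C or D or any E. coli control. The 27 genes changed on average in the gut became 3 with RLE, 5 with no filter, 172 with DESeq2 and 0 with limma-trend on TPM. With a library left out they became 0 to 182: 182 without P. aeruginosa control A, 97 without E. coli control C, and 0 without P. aeruginosa control D, P. aeruginosa infected A or E. coli control B. It was 5 and 16 without P. aeruginosa control B and infected B, 8 without P. aeruginosa infected D, 10 without E. coli control A, and 13, 2 and 1 without E. coli infected A, B and C. In the body 0 became 5 with DESeq2, 25 with limma-trend on TPM, and 0 to 1 with a library left out (1 without P. aeruginosa infected C).

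The median percentile of the 3 effectors was 47.8 in P. aeruginosa and 61.2 in E. coli guts on CPM, where lengths have no part, in place of 79.9 and 89.0 on TPM, and 81.9 in E. coli guts among genes with a mean TPM of at least 1, a smaller set. With a control body left out it ran from 0 (without B) to 23.2 in the P. aeruginosa bodies.

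Uncalled effectors changed sign when 1 library was left out. Defensin-1 gave -0.0017 in P. aeruginosa gut without infected A (range to 1.95), -0.14 in P. aeruginosa body without infected B (range to 1.11), and -0.10 and -0.16 in E. coli gut without control C and infected B (range to 0.25). Lysozyme gave -0.17, -0.20 and -0.52 in P. aeruginosa gut without control B, control C and infected D (range to 0.73), and -0.062 in E. coli gut without infected B (range to 0.68). Genes with TPM sign changes above were not counted. Of other values 41 newly passed, 1 (defensin-1, P. aeruginosa controls) no longer did, and the rest kept direction and side. With a replicate block over the E. coli experiment (2 letters from the TPM match) edgeR called 0 genes in gut (1006 at an unadjusted p under 0.05), 0 in body (390), 0 for the difference between tissues (533) and 7133 between control tissues, and 0 lists passed camera. With a block by treatment and letter it called 7259 between control tissues and 0 for the difference between tissues (573).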

Other observations

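The mean of both gut responses, the mean of both body responses and the tests of both as counts were added after the correlation between the experiments had been seen. The class of body genes was prompted by yp3, para-like, nAChRbeta3 and SPN15, whose values had been seen, and the margin used to read its test in bodies was added after that value was seen. With 3 comparisons added to the 10 planned and 27 tests made, some results past a threshold are to be expected by chance.

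At an unadjusted p under 0.05, 108 genes were lower in both gut comparisons where independence gives 29.0, of which 89 were called body-higher in both sets of controls, and 15 were higher in both where independence gives 4.25. In the bodies 7 were higher in both (3.17 by independence) and 0 lower in both (1.37). These overlaps carry no test of their own, since genes are not independent.

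Over 11346 genes, the log2 differences between infected and control guts in the 2 experiments had a correlation of 0.325, reached in 12 of 1400 joint relabellings (highest of the others 0.352). Genes are not independent replicates, and the relabelling keeps their dependence. Without the genes called body-higher it was 0.245 over 6947 genes, reached in 12 of 1400. In the bodies it was 0.171, reached in 230 of 1400 (highest of the others 0.403), so a shared body response was not shown. A shared gut response may exist, as a hypothesis, but anything that differed between infected and control guts in both experiments, dissection included, would give the same correlation.

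The body genes could be lower because less carcass tissue was left on the infected guts. Genes at least 8-fold higher in body than gut of the other experiment's controls had a median log2 difference of -0.63 in P. aeruginosa guts (741 genes) and -0.47 in E. coli guts (506 genes), and 17 of 1400 joint relabellings (1.21%) gave a sum as low, while alone 5 of 70 gave as low a median in P. aeruginosa guts and 3 of 20 in E. coli guts, so for this class neither experiment passes 5% by itself and the joint share is for a class prompted by the data. Genes at least 64-fold higher lay at -0.60 in P. aeruginosa guts (1 of 70 as low, the real labelling) and at -0.16 in E. coli guts (6 of 20). Loss of carcass had been predicted to place them at least as low as the 8-fold class, and in neither experiment did they lie so low. The SDs of their medians over relabellings were 0.312 and 0.159. The step between the classes was not itself relabelled, so it does not decide on loss of carcass. A regulation of the whole class by infection predicts the same shift in bodies, where the higher median of the 8-fold class was -0.082, less than its SD over relabellings of 0.146, but the 64-fold class lay at -0.27 with P. aeruginosa (7 of 70 as low) and at -0.32 with E. coli (2 of 20). Loss of carcass and regulation therefore cannot be told apart here, since the tissue left at dissection was not measured.

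In the joint edgeR fit, 27 genes were changed on average by both bacteria in the gut (2 higher, 25 lower, 987 at an unadjusted p under 0.05), of which 20 of the 25 lower were called body-higher in both sets of controls. They include yp3 (log2 -4.61 ± 0.83, adjusted p = 0.0420), with LOC101897883 (-2.36 ± 0.38) and LOC101890151 (-2.97 ± 0.50) at the smallest p, and LOC101899804 (0.81 ± 0.17) and LOC101899302 (0.94 ± 0.20) as the higher ones. With relabelled libraries 3 of 50 splits, 6%, gave as many, the highest of the others 259, so chance is not excluded, and limma-trend on TPM called 0 where DESeq2 called 172. With 1 library left out the count ran from 0 (without P. aeruginosa control D, P. aeruginosa infected A or E. coli control B) to 182 (without P. aeruginosa control A), so the call does not hold without single libraries. In the body edgeR called 0 (405 at an unadjusted p under 0.05, where chance gives about 600, 5 by DESeq2, 25 by limma-trend on TPM). Diptericin, which this joint fit did test, gave log2 1.31 ± 1.24 for the mean of both body responses (edgeR unadjusted p = 0.303). A count of 0 is reached by every split, here 50 of 50, and the highest of the others was 54.

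Other splits of the libraries were counted for each planned comparison, and where the real count was 0 every split gives as many, so those shares decide nothing. Between gut and body of P. aeruginosa controls 1 of 35 splits, the real one with 5498 genes, gave as many and the highest of the others 0. This share is under 5% and the smallest that 35 splits allow. Every other split mixes guts with bodies in both groups, which widens their spread, so the share alone does not exclude chance. For the E. coli controls it was 1 of 10 with 7322 genes and 0, too few splits for a share under 5%. For P. aeruginosa gut and body, with 0 genes, 35 of 35 splits gave as many, the highest of the others 2424 and 65, and a split with 2424 points to a structure of the samples. That split set control gut A and infected guts A, B and D against the other guts. They were the guts with the least bcd RNA, at most 3.34 in log2 CPM against at least 4.03 in the others. The cause of that structure was not tested. For E. coli gut and body, with 0 genes, 10 of 10 gave as many, the highest of the others 2 and 2, again with too few splits for a share under 5%. For the differences between tissues, with 0 genes, 100 of 100 gave as many, the highest of the others 718 for P. aeruginosa and 3 for E. coli. For the differences between bacteria, with 0 genes, 50 of 50 gave as many, the highest of the others 1505 in the gut and 32 in the body.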
